A study of Mus musculus with 12 samples.

How the data were processed

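Total RNA from the atria of 6 Tbx3 (Cre4-CT) and 6 Control (Cre4) mice was extracted on columns, amplified and biotin-labelled from small inputs and hybridised to Illumina Sentrix Mouse-6 beadchips, per the labels' protocols. Groups and replicate numbers were taken from the sample titles, and the descriptions call the samples biological replicates. The authors deposited a table with a log-scale value per probe and array. Their background step, their normalization and the log base are not given in the sources used here. The deposited values are taken as natural log values, which is an inference from the data. They ran from 2.63 to 10.81 with a median of 3.87, which on base e is 13.9 to 49513 with a median of 47.9, the top just under the 16-bit scanner ceiling of 65535. On base 2 the brightest probe would reach 1795. The SD between replicates was also nearly flat over the range, with a median of 0.132 for the dimmer part of the probes and 0.107 for the brightest 1%, as after a variance-stabilising transform. Such a transform, or background left in the values, would make the folds of dim probes smaller than the true ones. All values were divided by the natural log of 2 to give log2 levels. If the table were in base 2, log2 changes would be 0.693 times as large and folds smaller, while p-values would not change.

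The table held 46133 rows, of which 10 were empty, and 9 more repeated all 12 values of another row and were dropped, which left 46114 probes. No detection p-values were used, so whether a probe lay above background is unknown, and the percentile of its mean among all probes is given where a dim probe matters. Array medians differed by 0.087 log2 at most, but interquartile ranges, from 0.54 to 0.65 in deposited units, differed by 20.4%. The rule fixed in advance, a difference over 0.1 log2 in medians or over 10% in interquartile ranges, therefore called for quantile normalization, which was applied (limma normalizeQuantiles). No pair of arrays had identical columns, and correlations over all probes ran from 0.970 to 0.980 within groups and from 0.963 to 0.976 between groups.

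Probes were named through the platform annotation, with symbols updated through gene identifiers or accessions against a RefSeq gene table of the GRCm38.p6 assembly. Of the 46114 probes, 29534 (64%) had 1 gene symbol, 11 had several and 16569 had none, and the last 2 kinds were tested but not named. A gene was represented by the probe with the highest mean over all arrays, which gave 17655 genes. For 125 genes 2 or more probes passed, and for 2 genes different probes were called in opposite directions.

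The comparison was Tbx3 minus Control in limma (lmFit and eBayes, 2-sided, total degrees of freedom 28.4), with Benjamini-Hochberg adjustment over all probes and a threshold of 0.05. Gene lists, 16 of pathways and 14 of cell types, were fixed before the data were examined, as were 10 families defined by the start of the symbol. They were tested with camera at its preset inter-gene correlation of 0.01, 1 probe per gene, and again with a correlation estimated from the data, with adjustment over the 30 lists and separately over the families. Errors are SDs between arrays for levels and standard errors of the fit for changes. Counts of genes in a list are adjusted over all probes unless they are said to be adjusted over the list alone.

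The genes named in the text followed a rule also fixed beforehand. It takes the 12 largest rises and the 12 largest falls among genes past the threshold whose groups did not overlap, up to 4 members of each list with the smallest p among those past the threshold or up to 2 given as values, up to 3 members of each family, and 25 genes named whatever they showed, such as Tbx3, Tbx2, Nppa, Gja1 and Hcn4. Some of these 25 genes are not reported here.

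On simulated data with 200 of 46114 probes changed, drawn with the spread of these arrays, the test recovered 6% of probes changed 1.25-fold, 76% at 1.5-fold, 94% at 2-fold and 100% at 3-fold, with 10 false calls (6.76% of calls). Camera called 10 of 10 simulated lists shifted by 0.2 log2 and 1 of 30 unshifted lists. The simulated probes were drawn independently of each other, so these counts do not show how camera behaves where genes are correlated. The alternatives tried were the table as deposited, median centring, 2 filters on dim probes, array weights and a robust intensity trend. Blocks by replicate number and by odd or even number, stricter thresholds and the mean of all probes of a gene were also tried. The last were the rotation test fry and each array left out in turn. The robust intensity trend joins an intensity trend in the variance with the robust option of limma in the gene tests, and they were not tried apart. Under a filter on dim probes a list median covers only the members whose probes were kept. Alternatives chosen after seeing the data kept the repeated rows, read the table in base 2, left out Control array 4 and Tbx3 array 6 together, or took the mean of the erythroid list as a covariate. The chip of each array is not given in the sources used here. Work was done in R 4.3.3 with limma 3.58.1 and in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.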

Results

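Gene expression was measured in the atria of 12 male mice on Illumina Sentrix Mouse-6 beadchips, on which each gene is read by oligonucleotide probes attached to beads. The 6 Tbx3 mice carried both the Nppa-Cre4 transgene, which drives Cre recombinase in atrial muscle, and a construct (CT) from which Cre activates Tbx3, a T-box transcription factor that represses transcription. The 6 Control mice carried the Cre4 transgene alone. The labels call the arrays of a group biological replicates, so each array stands for a separate animal. The deposited table gave a value for 46114 distinct probes in every sample, and the number of arrays limits the precision. The series title names the question, which is how Tbx3 and its relative Tbx2 act on a nodal, meaning pacemaker-like, phenotype and on the formation of endocardial cushions. Here the atria of the Tbx3 mice were compared with the Control atria. No group carried the CT construct without Cre, so effects of the construct itself cannot be told apart from those of activated Tbx3.

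Cntn2, a cell adhesion molecule of neurons and of conduction fibres, showed the largest rise in the Tbx3 atria, 6.34-fold, from a log2 level of 6.05 ± 0.51 (SD, n = 6) in Control to 8.72 ± 0.33 (SD, n = 6). Tnni2, the troponin I of fast skeletal muscle, showed the largest fall, 9.71-fold, from 9.19 ± 0.99 to 5.91 ± 0.46 (SD, n = 6 each). The size of this fold is uncertain. The Tbx3 mean lay near the median of all probes, 5.55, and the Control arrays ran from 7.403 to 10.185. Of 25 genes of working heart muscle 11 fell, among them the natriuretic peptide genes Nppa and Nppb and the connexin genes Gja1 and Gja5. Of the pacemaker and conduction genes 10 of 28 rose, of the cushion formation genes 10 of 41 and of the extracellular matrix genes 24 of 47. Falls were found for 8 of 33 genes of fatty acid oxidation and 10 of 53 of oxidative phosphorylation. All folds and log2 values read the deposited table as natural logs, a base inferred from its range. Were it base 2, each log2 change would be 0.693 times as large, with the same p-values.

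Across all probes, 1592 of 46114 (3.45%) passed an adjusted p of 0.05 in limma, 817 of them higher and 775 lower in the Tbx3 atria. Counted by gene, with the brightest probe standing for each of 17655 genes, 524 rose and 527 fell. The groups did not overlap for 713 of the 17655 genes, where chance alone would separate 0.216%, and 585 of these 713 were among the 1051 past the threshold. The median size of the change among the genes past the threshold was 0.51 on the log2 scale, and 35 genes rose and 37 fell at least 2-fold. A further 323 probes past the threshold had no gene symbol in the annotation used here. The median change of all probes was -0.0010.

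**Figure D1:**
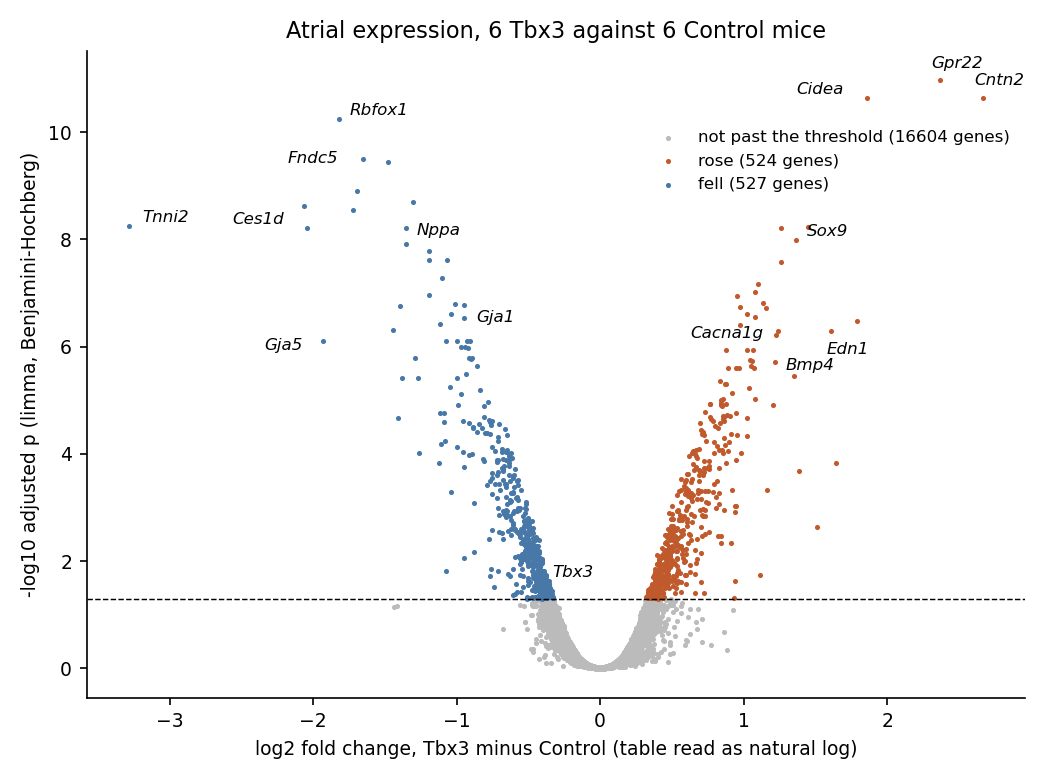
Change in expression of each gene (horizontal axis, log2 fold change, Tbx3 minus Control) against the evidence for it (vertical axis, -log10 of the limma adjusted p), 1 point per gene, with the dashed line at an adjusted p of 0.05. Of 17655 genes, 524 rose and 527 fell, and Cntn2 and Tnni2 lie at the ends of the horizontal axis.

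Of 25 measured genes in the list for working myocardium, 11 fell, 1 rose and 13 did not pass the test. Nppa, which encodes atrial natriuretic peptide, fell by 1.35 on the log2 scale (SE 0.12), from 13.58 ± 0.16 to 12.23 ± 0.30 (SD, n = 6 each, adjusted p = 1.2e-08). Nppb, the gene of the related B-type peptide, fell by 1.38 (SE 0.17, adjusted p = 3.82e-06). Among the connexins, the proteins of gap junctions, Gja1 (connexin 43) fell by 0.95 (SE 0.10, adjusted p = 2.94e-07) and Gja5 (connexin 40) fell by 1.93 (SE 0.22, adjusted p = 7.95e-07). In all 4 genes every Tbx3 array lay below every Control array. Of the 4 probes for Gja5 only the brightest was called, and their mean changed by -0.65 (adjusted p = 0.000367). The gene that rose was Kcnj5, a potassium channel subunit, at a log2 change of 0.40, and its call was lost without any of 5 single arrays, those of Control 4 and 6 and of Tbx3 2, 3 and 6 (adjusted p up to 0.0879), and without Control 4 and Tbx3 6 together (adjusted p = 0.174). Kcnj5 and the few other genes named outside the fixed rule were chosen after their values were seen. Adjusted over the list alone, 12 genes fell and 2 rose. The list as a whole shifted down (median log2 change -0.24, camera adjusted p = 1.59e-08, and adjusted p = 0.0173 with an estimated correlation). The median was -0.13 with the mean of all probes of a gene, -0.14 with the erythroid mean as a covariate and -0.44 under the stricter filter on dim probes. In the same arrays the fibroblast markers were higher (median log2 change 0.31, camera adjusted p = 6.55e-08, and adjusted p = 0.0339 with an estimated correlation), and so were the erythroid markers (median log2 change 0.60, camera adjusted p = 0.00283, but adjusted p = 0.258 with an estimated correlation). Kcnj2, which carries the inward rectifier current, and Bmp10 had log2 changes of -0.06 and -0.02 (adjusted p of 0.933 and 0.982), and both probes were dim, at the 52.4th and 46.4th percentile of all probes.

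Of 28 measured pacemaker and conduction genes, 10 rose, 1 fell and 17 did not pass, and adjusted over the list alone 10 rose and 2 fell. Beside Cntn2 (log2 change 2.67, SE 0.17, adjusted p = 2.3e-11), the T-type calcium channel gene Cacna1g rose by 1.24 (SE 0.14, adjusted p = 5.17e-07), the calcium sensor gene Vsnl1 by 1.16 (SE 0.12, adjusted p = 1.89e-07) and the transcriptional regulator Lbh by 1.02 (SE 0.11, adjusted p = 2.43e-07). The gene that fell was Fgf13, which encodes a modulator of sodium channels, at -0.78. With the mean of their probes Cacna1g, Vsnl1 and Fgf13 changed by 0.70, 0.64 and -0.45 and kept their calls. The list shifted up (median log2 change 0.13, camera adjusted p = 2.06e-06, and adjusted p = 0.0296 with an estimated correlation). The median was 0.07 with the mean of all probes of a gene and with the erythroid mean as a covariate, and 0.44 under the stricter filter on dim probes. Several pacemaker genes did not pass. Hcn4, the main pacemaker channel gene, had a log2 change of -0.09 (adjusted p = 0.866), and its probe lay at the 26.3rd percentile of brightness. The transcription factor genes Isl1, Shox2 and Tbx18 had log2 changes of -0.10, 0.15 and 0.04 (adjusted p of 0.841, 0.666 and 0.957), and Bmp2 had -0.17 (adjusted p = 0.712). The probes of Isl1 and Bmp2 were dim, at the 53.1st and 50.3rd percentile, and those of Shox2 and Tbx18 lay at the 64.8th and 76.4th. The fibroblast and erythroid markers given above were higher in the same arrays.

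**Figure D2:**
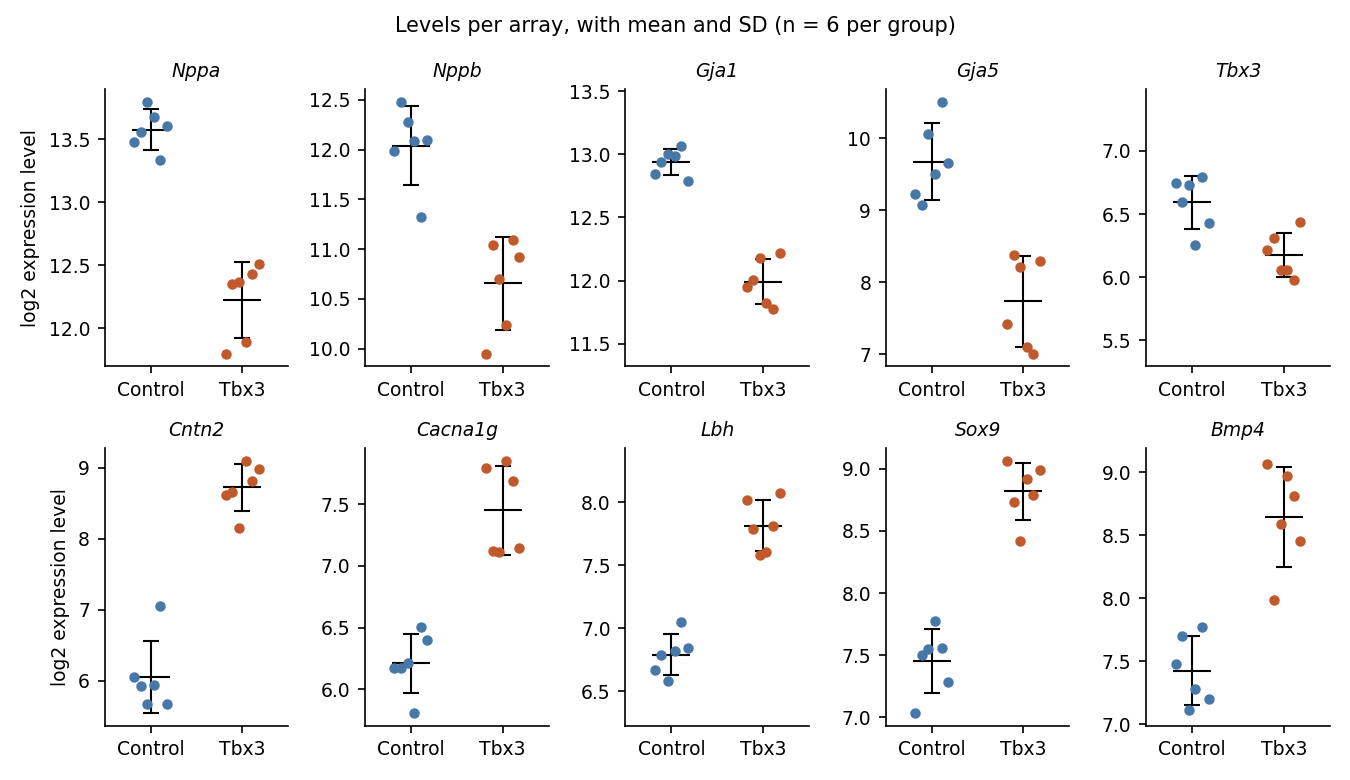
Log2 expression level (vertical axes, each with its own range and not starting at 0) of 10 genes in the 6 Control and 6 Tbx3 arrays, 1 point per array, with the group mean and SD as bars. For Nppa, Nppb, Gja1, Gja5, Cntn2, Cacna1g, Lbh, Sox9 and Bmp4 the groups do not overlap, while for the mouse Tbx3 probe, with a mean of 6.59 in Control and 6.18 in Tbx3, they do.

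The brighter of the 2 probes for mouse Tbx3 did not show the activated transgene. Its log2 level was 6.59 ± 0.21 in Control and 6.18 ± 0.18 in the Tbx3 arrays (SD, n = 6 each), a change of -0.42 (SE 0.11, adjusted p = 0.0263). This call was lost without any of 6 single arrays, those of Control 1, 3 and 5 and of Tbx3 3, 4 and 5 (adjusted p up to 0.0852), and when both probes were averaged (log2 change -0.20, adjusted p = 0.245). The dimmer probe stood at 5.42 ± 0.15 and 5.44 ± 0.23. Where either probe lies relative to the transgene is not known here, so Tbx3 does not check the group labels. Tbx2 had a log2 change of -0.03 (adjusted p = 0.965), and Tbx5 had 0.03 (adjusted p = 0.975). The Tbx2 probe lay at the 64.2nd percentile of brightness, with means of 5.78 in Control and 5.75 in Tbx3 against a median of 5.55 over all probes. Of 11 T-box genes, Tbx3 alone passed, also when adjusted over the list alone.

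Among 36 cardiac transcription factor genes, 5 rose and 5 fell, and the list did not shift (camera adjusted p = 0.936). Id2 and Id3, which encode inhibitors of DNA binding, rose by 0.77 (SE 0.11) and 0.81 (SE 0.12), with adjusted p of 2.02e-05 and 7.24e-05. The homeobox genes Hopx and Prox1 fell by 0.89 (SE 0.14) and 0.72 (SE 0.12), with adjusted p of 0.000102 and 0.00014. The mean of both Hopx probes gave -0.41, with an adjusted p of 0.0719. Nkx2-5 had a log2 change of -0.15 (adjusted p = 0.712). Adjusted over the list alone, 7 genes rose and 6 fell.

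In the list for cushion formation and the transition from epithelium to mesenchyme, 10 of 41 measured genes rose, 0 fell and 31 did not pass. Sox9, a transcription factor of cushion mesenchyme and cartilage, rose 2.58-fold (log2 change 1.37, SE 0.12, adjusted p = 1.04e-08). The growth factor genes Bmp4, Tgfb2 and Bmp6 rose by 1.22, 0.66 and 0.62 on the log2 scale (SE 0.15, 0.10 and 0.10), with adjusted p of 1.89e-06, 9.88e-05 and 0.00011. With the mean of its probes Bmp4 changed by 0.75 (adjusted p = 0.00138). The list shifted up (median log2 change 0.18, camera adjusted p = 2.54e-06, and adjusted p = 0.0173 with an estimated correlation), and adjusted over the list alone 16 genes rose and 1 fell. The median was 0.06 with the mean of all probes of a gene and 0.30 under the stricter filter on dim probes. Has2, the hyaluronan synthase of the cushions, and Postn, which encodes periostin, had log2 changes of -0.06 and 0.30 (adjusted p of 0.929 and 0.704). The higher fibroblast markers (median log2 change 0.31) moved with this list too.

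The extracellular matrix list held the largest share of genes that rose, 24 of 47, while 1 fell and 22 did not pass. Loxl1, an enzyme that crosslinks elastin, rose by 0.80 (SE 0.11, adjusted p = 2.98e-05), Col14a1 by 0.86 (SE 0.12, adjusted p = 2.04e-05), the proteoglycan gene Lum by 0.83 (SE 0.13, adjusted p = 8.44e-05) and the microfibril gene Mfap5 by 0.94 (SE 0.15, adjusted p = 0.000127). Ccn4, a secreted matrix-associated protein, fell by 0.81. Adjusted over the list alone, 31 genes rose and 1 fell. The list shifted up (median log2 change 0.43, camera adjusted p = 9.15e-19, and adjusted p = 0.0339 with an estimated correlation). In the collagen family 14 of 40 genes rose and 0 fell, or 18 and 0 adjusted over the list alone. The smallest p-values were those of Col4a6 (1.23, SE 0.14, adjusted p = 6.16e-07), Col14a1 and Col16a1 (0.67, SE 0.11, adjusted p = 0.000178), and Col1a1 rose more than the last 2 (0.94, SE 0.18, adjusted p = 0.000945). With the mean of their probes Col4a6 and Ccn4 changed by 0.59 and -0.42 and kept their calls. The family shifted up with the preset correlation (camera adjusted p = 7.05e-09), which was lost with an estimated correlation (adjusted p = 0.0621). Markers of fibroblasts, which share 7 of their 16 genes with the matrix list, moved with these genes. Of the 16, 6 rose and 0 fell (8 and 0 adjusted over the list alone), among them Dpt (0.88, SE 0.12) and S100a4 (1.02, SE 0.15), and the list shifted up (median log2 change 0.31, camera adjusted p = 6.55e-08, and adjusted p = 0.0339 with an estimated correlation). With the erythroid mean as a covariate the median was 0.20.

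In mitochondrial metabolism the calls were falls. Of 33 genes of fatty acid oxidation, 8 fell, 0 rose and 25 did not pass, with 12 falls adjusted over the list alone. Cpt1b and Cpt2, the carnitine palmitoyltransferases that carry fatty acids into mitochondria, fell by 0.71 (SE 0.12) and 0.64 (SE 0.10), with adjusted p of 0.000358 and 0.000101. The coactivator gene Ppargc1b fell by 0.75 (SE 0.13) and the thiolase gene Acaa2 by 0.57 (SE 0.11). Of 53 genes of oxidative phosphorylation 10 fell, 0 rose and 43 did not pass, with 26 falls adjusted over the list alone. The complex I genes Ndufs7, Ndufb3 and Ndufv1 fell by 0.55, 0.47 and 0.43, and Cox8b of complex IV fell by 0.53 (SE 0.10 each, adjusted p of 0.000461, 0.00259, 0.00867 and 0.00199). Both lists shifted down with the preset correlation. The median log2 change was -0.25 for fatty acid oxidation (camera adjusted p = 1.7e-10) and -0.26 for oxidative phosphorylation (camera adjusted p = 2.61e-17), and neither call held with an estimated correlation (adjusted p of 0.0668 and 0.0525). In the same arrays the fibroblast markers were higher, as given above, and so was the erythroid list with the preset correlation alone (median log2 change 0.60). Of 20 glycolysis genes 3 rose and 1 fell (5 and 2 adjusted over the list alone), and the list did not shift (camera adjusted p = 0.228). Pfkfb2, a regulator of glycolysis, fell by 0.62 (SE 0.11, adjusted p = 0.000759), or by 0.29 with the mean of its probes (adjusted p = 0.0209), and Pgam1, a glycolytic mutase, rose by 0.66 (SE 0.15, adjusted p = 0.00607). The glucose transporter gene Slc2a1 and the phosphofructokinase gene Pfkp rose by 0.36 and 0.39. The call of Slc2a1 was lost without any of 9 single arrays, all but Control 1 and 4 and Tbx3 6 (adjusted p up to 0.0906), and that of Pfkp without any of 8, all but Control 1 and 5 and Tbx3 5 and 6 (adjusted p up to 0.134). Pfkp has 5 probes, of which 1 was called, and their mean changed by 0.13 (adjusted p = 0.343). Without Control 4 and Tbx3 6 together the adjusted p of Pfkp was 0.0869.

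**Figure D3:**
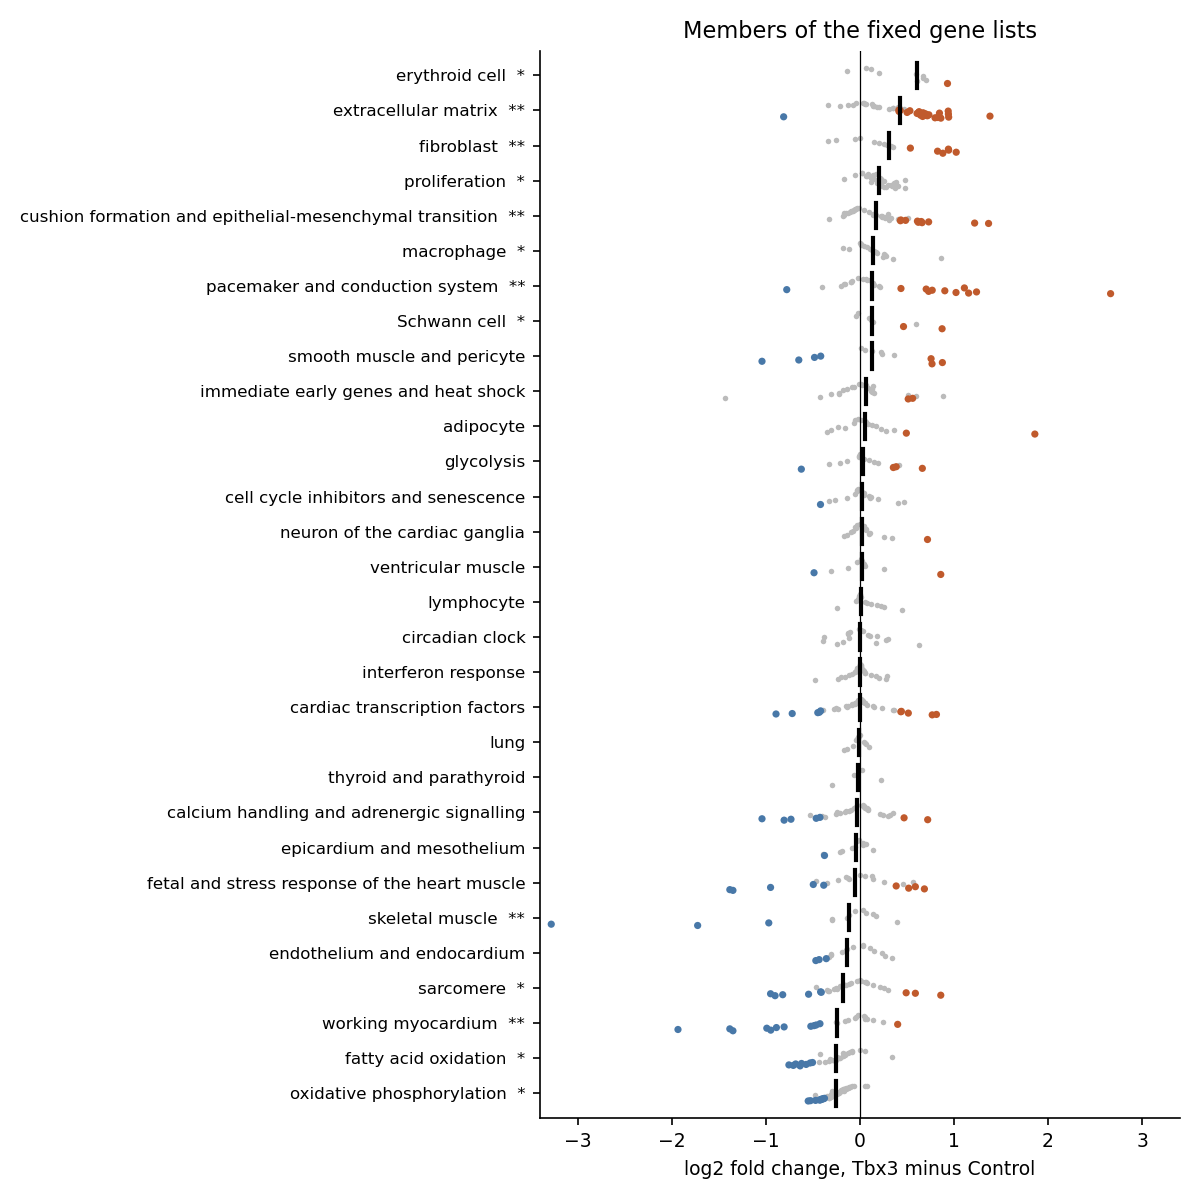
Log2 fold change (horizontal axis, Tbx3 minus Control) of the members of the 30 fixed gene lists, 1 list per line and 1 point per gene, coloured where the gene rose (orange) or fell (blue) and grey where it did not pass. Black bars are list medians, and stars mark the 13 lists called by camera with its preset correlation. A pair of stars marks the 6 of them also called with an estimated correlation, and 1 star marks the rest.

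Contractile genes went both ways. Of 33 sarcomere genes 3 rose and 6 fell, and adjusted over the list alone 4 rose and 11 fell. Mybphl, a myosin-binding protein of the atria, fell by 0.90 (SE 0.11, adjusted p = 1.69e-06), Myom2 of the M-band by 0.82 (SE 0.12, adjusted p = 3.28e-05) and Ttn, the gene of titin, by 0.55 (SE 0.12, adjusted p = 0.00721), or by 0.33 with the mean of its probes (adjusted p = 0.0122). Myl2, the regulatory light chain typical of ventricular muscle, rose by 0.86 (SE 0.12, adjusted p = 1.95e-05). The downward shift of the list (median log2 change -0.18, camera adjusted p = 0.0131) was lost with an estimated correlation (adjusted p = 0.264), with the rotation test fry (adjusted p = 0.0514) and with the erythroid mean as a covariate (adjusted p = 0.148), and the median was -0.06 with the mean of all probes of a gene. In Tbx3 array 2 the mean of the sarcomere list, 10.45, lay above every Control array, which ran from 10.34 to 10.41. Among 13 genes of skeletal muscle 3 fell and 0 rose, namely Tnni2 (-3.28, SE 0.28), Atp2a1 (-1.72, SE 0.14), the calcium pump of fast fibres, and Ckm (-0.97, SE 0.11), the muscle creatine kinase that heart muscle also expresses. Adjusted over the list alone, 5 fell and 1 rose. This list shifted down (median log2 change -0.12, mean -0.47, camera adjusted p = 0.00247, and adjusted p = 0.0413 with an estimated correlation). Its median was -0.05 without Control array 4, -0.07 without Tbx3 array 3, -0.04 without Control 4 and Tbx3 6 together and -1.35 under the stricter filter on dim probes. That filter left only the members with bright probes, among them Tnni2, Atp2a1 and Ckm, so this median does not stand for the whole list. The fibroblast list (median log2 change 0.31) and, with the preset correlation alone, the erythroid list (0.60) were higher in the same arrays. Of 10 ventricular genes Myl2 rose and the potassium channel gene Kcnd2 fell by 0.49 (SE 0.11, adjusted p = 0.00829), with 1 rise and 2 falls adjusted over the list alone, and the list did not shift (camera adjusted p = 0.936). In the fetal and stress response list 4 of 22 genes rose and 5 fell (6 and 6 adjusted over the list alone), with no shift (camera adjusted p = 0.823). Nppa and Nppb were among the falls, while Timp1, an inhibitor of metalloproteinases, and Actn1, an actinin of non-muscle cells, rose by 0.69 (SE 0.11) and 0.52 (SE 0.11).

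Genes of calcium handling and of ion channels also moved in either direction. Of 34 calcium handling and adrenergic genes 2 rose and 5 fell, or 4 and 8 adjusted over the list alone (camera adjusted p = 0.27). Sln, the gene of sarcolipin, an inhibitor of the calcium pump, fell by 0.81 (SE 0.12) and Hrc, which binds calcium in the sarcoplasmic reticulum, by 0.73 (SE 0.11), while the calcium channel subunit gene Cacnb2 rose by 0.72 (SE 0.11), with adjusted p of 4.07e-05, 8.69e-05 and 4.51e-05. Rgs5 fell by 1.04 (SE 0.18, adjusted p = 0.000508). Its call was lost with the robust intensity trend (adjusted p = 0.0685) and with the mean of its probes (adjusted p = 0.839). In the calcium channel family 4 of 23 genes rose and 0 fell, namely Cacna1g, Cacnb2, Cacna2d2 (0.71, SE 0.16) and Cacna1h (1.11), with the same counts adjusted over the list alone. The mean of the Cacnb2 probes changed by 0.29 (adjusted p = 0.0143). The Cacna1h probe, dim in Control with a mean of 5.38 against a median of 5.55 over all probes, stood at 7.40 in Control array 4 and between 4.74 and 5.09 in the other Control arrays, and its call was lost without Control array 1, Control array 2 or Tbx3 array 6 (adjusted p of 0.0543 to 0.0584). The calls of Cacna2d2 and Cacna1h were lost with the robust intensity trend (adjusted p of 0.121 and 0.322) and with the mean of their probes (adjusted p of 0.113 and 0.0573). Of 86 potassium channel genes 5 rose and 7 fell, and adjusted over the list alone 7 rose and 10 fell. Kcnj3, a subunit of the acetylcholine-activated channel, fell by 0.99 (SE 0.13), Kcnv2 fell by 0.68 (SE 0.11), and Kcnh2, the gene of the rapid delayed rectifier, rose by 0.74 (SE 0.14), or by 0.46 with the mean of its probes (adjusted p = 0.00396). Of 10 sodium channel genes Scn10a fell by 0.77 (SE 0.11, adjusted p = 2.58e-05) and Scn7a rose by 0.49 (SE 0.11, adjusted p = 0.00599). Of 14 gap junction genes Gja1 and Gja5 fell and Gjc1 (connexin 45) rose by 0.44 (SE 0.10, adjusted p = 0.0115), which was lost with the mean of its probes (adjusted p = 0.0898). For the sodium channel and gap junction genes the counts were the same adjusted over the list alone. Camera called none of these 4 families (adjusted p of 0.273, 0.409, 0.864 and 0.487, in the order given). The rotation test fry, which does not compare a family with other genes, called calcium channels upward (mean log2 change 0.14, adjusted p = 0.00132), potassium channels downward (mean -0.04, adjusted p = 0.0142) and gap junction genes downward (mean -0.16 but median 0.03, adjusted p = 0.022).

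Several of the 12 largest rises lay outside these lists. Gpr22, an orphan G protein-coupled receptor, rose 5.16-fold (log2 change 2.37, SE 0.14), Edn1, the precursor of the vasoconstrictor endothelin 1, 3.05-fold (1.61, SE 0.18) and Plppr5, a brain-expressed phospholipid phosphatase-related protein, 2.73-fold (1.45, SE 0.12). The Control means of Gpr22 and Plppr5, 5.09 and 5.48, lay below the median of all probes, 5.55, so these folds start from dim levels. The chemokine genes Ccl21c and Ccl21a rose 3.47-fold and 2.56-fold. They are near-identical copies, so their probes can read the same transcripts. The receptor subunit gene Il13ra1 and the adhesion gene Kirrel3 each rose 2.40-fold. Among the 12 largest falls, the RNA-binding protein gene Pum3 fell 4.18-fold (log2 change -2.06, SE 0.17), but its other probe was not called and their mean changed by -0.98. The carboxylesterase gene Ces1d fell 4.12-fold (-2.04, SE 0.18), the splicing regulator Rbfox1 3.53-fold (-1.82, SE 0.12), Fgf12, a modulator of sodium channels, 3.24-fold (-1.69, SE 0.13) and Fndc5, a membrane protein of muscle, 3.15-fold (-1.65, SE 0.12). Nudt8, Sema6c, Lamb3 and Pla2g4e fell 2.79-fold, 2.72-fold, 2.65-fold and 2.63-fold. Of the probes for Kirrel3 1 of 2 was called, of those for Sema6c and Pla2g4e 1 of 3 each and of those for Rbfox1 2 of 3. The means over their probes changed by 0.67, -0.59, -0.43 and -0.98 and kept the calls (adjusted p up to 0.00896). By their brightest probes all the genes of this paragraph had adjusted p between 1.07e-11 and 2.1e-05. Had probes without a symbol been ranked, 3 would stand among the rises and 4 among the falls.

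Markers of other cell types differed by type. Of 17 endothelial genes 0 rose and 3 fell (2 and 5 adjusted over the list alone), namely Flt1 (-0.47, SE 0.10), Plvap (-0.43, SE 0.10) and Esam (-0.36, SE 0.09), and the list did not shift (camera adjusted p = 0.158), but it passed without Control 4 and Tbx3 6 together (median log2 change -0.21, adjusted p = 0.042). The call of Esam was lost without any of 4 single arrays, those of Control 5 and Tbx3 2, 3 and 4 (adjusted p up to 0.0634). Of 13 genes of smooth muscle and pericytes 3 rose and 4 fell, or 4 and 4 adjusted over the list alone (camera adjusted p = 0.299, but 0.0332 with the mean of all probes, at a median log2 change of 0.13). The contractile genes Tagln, Acta2 and Myh11 rose by 0.77, 0.88 and 0.76, or by 0.41, 0.56 and 0.44 with the mean of their probes (adjusted p of 0.00319, 0.0138 and 0.0359), and Tagln was dim in Control, at 5.18 against a median of 5.55 over all probes. In contrast Rgs5, the channel genes Kcnj8 and Abcc9, which mark pericytes, and Smtn fell by 1.04, 0.65, 0.48 and 0.42. With the mean of all probes Abcc9 and Smtn had adjusted p of 0.85 and 0.8, and the call of Smtn was lost without any of 4 single arrays, Control 5 and 6 and Tbx3 5 and 6 (adjusted p up to 0.0829), and without Control 4 and Tbx3 6 together (adjusted p = 0.0553). The erythroid list was higher in the Tbx3 arrays (median log2 change 0.60, camera adjusted p = 0.00283, lost with an estimated correlation at adjusted p = 0.258 and with fry at adjusted p = 0.137, and a median of 0.34 without Control array 4), with Slc4a1, the anion exchanger of red cells, past the threshold at 0.93 (adjusted p = 0.0484) and the haemoglobin gene Hbb-b2 at 0.61 (adjusted p = 0.111). Slc4a1 was the only call among 10 erythroid genes, and adjusted over the list alone 6 rose. The call of Slc4a1 was lost without any of 8 single arrays, all but Control 1 and 6 and Tbx3 2 and 6 (adjusted p up to 0.178). It was also lost with the robust intensity trend (adjusted p = 0.422) and in the fit on the mean of probes of each gene (0.15). Either filter on dim probes lost it too (0.0675 and 0.0637). Slc4a1 has 1 probe, so its log2 change stayed at 0.93 in the fit on probe means. Hbb-b2 passed without Control array 1 (0.73, adjusted p = 0.0415). The macrophage list shifted up with the preset correlation (median log2 change 0.14, camera adjusted p = 0.015, but adjusted p = 0.474 with an estimated correlation), with 0 of 18 genes past the threshold under either adjustment, and its call was also lost without Control array 5, Tbx3 array 1 or Tbx3 array 5 (adjusted p of 0.0512 to 0.0764), under the stricter filter on dim probes (adjusted p = 0.146), with fry (adjusted p = 0.175) and with the erythroid mean as a covariate (adjusted p = 0.292). Of 18 adipocyte genes Cidea, a lipid droplet protein of brown fat, rose 3.63-fold and Fasn, the fatty acid synthase, rose by 0.49 (SE 0.10), with 3 rises and 1 fall adjusted over the list alone, and the list was not called by camera (median log2 change 0.06, adjusted p = 0.0888). It was called by the rotation test fry (adjusted p = 0.00205) and by camera under the stricter filter on dim probes (median log2 change 0.36, adjusted p = 0.0219). That filter left only Cidea, Fasn, Scd1, Pnpla2 and Acly of the list, and its median is the change of Scd1. Of 12 epicardial genes Lrrn4 fell by 0.38 (adjusted p = 0.037, up to 0.11 without any of 8 single arrays, all but Control 4 and 5 and Tbx3 2 and 4), a call also lost in the table as deposited and with median centring (adjusted p of 0.0727 and 0.0877). Adjusted over the list alone 2 epicardial genes fell. The epicardial list did not shift (camera adjusted p = 0.228), but it passed with the erythroid mean as a covariate (median log2 change -0.12, adjusted p = 0.0491). Of 15 lymphocyte, 12 lung and 4 thyroid genes 0 passed in limma, with 1 fall among the thyroid genes adjusted over the list alone, and none of these lists shifted (camera adjusted p of 0.299, 0.936 and 0.936).

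Cell cycle and stress lists held few calls. Of 34 proliferation genes 0 passed under either adjustment, while the list as a whole lay higher with the preset correlation (median log2 change 0.21, camera adjusted p = 0.00304), which was lost with an estimated correlation (adjusted p = 0.561), without Control array 3 or Tbx3 array 4 (medians of 0.14 and 0.10, adjusted p of 0.0574 and 0.15), under the stricter filter on dim probes (adjusted p = 0.0631), with fry (adjusted p = 0.478) and with the erythroid mean as a covariate (adjusted p = 0.148). The median of this list was 0.35 without Tbx3 array 2, 0.33 without Tbx3 array 6 and 0.38 without Control 4 and Tbx3 6 together. Of 17 genes of cell cycle inhibition and senescence Ccng1 fell by 0.43 (adjusted p = 0.0469, up to 0.151 without any of 8 single arrays, all but Control 1 and 4 and Tbx3 3 and 6), also the only call adjusted over the list alone. With the mean of its probes Ccng1 changed by -0.30 (adjusted p = 0.114), and with odd and even replicate numbers as a block its adjusted p was 0.0521. The inhibitor gene Cdkn1a had a log2 change of 0.47 (adjusted p = 0.218) and passed without Control array 4 (0.63, adjusted p = 0.0309) and without Control 4 and Tbx3 6 together (0.69, adjusted p = 0.0205). Of 25 immediate early and heat shock genes Ier3 and Dusp1 rose by 0.51 and 0.56, and the call of Dusp1 was lost without any of 4 single arrays, those of Control 5 and Tbx3 1, 3 and 6 (adjusted p up to 0.0775). It was also lost with the robust intensity trend (adjusted p = 0.184) and in the fit on the mean of probes of each gene (0.0584). Dusp1 has 1 probe, so its log2 change stayed at 0.56 in that fit and only the rows fitted and adjusted with it differed. Without Control 4 and Tbx3 6 together Ier3 and Dusp1 had adjusted p of 0.0903 and 0.103. Adjusted over the list alone, 2 of these genes rose and 1 fell. Of 18 circadian and 28 interferon genes 0 passed under either adjustment. These 4 last lists did not shift (camera adjusted p of 0.936, 0.535, 0.936 and 0.936). Of the 30 fixed lists 13 were called with the preset correlation and 6 with an estimated correlation, namely working myocardium, pacemaker and conduction system, cushion formation, extracellular matrix, fibroblast and skeletal muscle.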

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

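The tests of the Tbx3 probe in this part were chosen after the results were seen. In 314 sets of 6 arrays, 20 arrays stood far from the other 5 of their group, where chance flags about 1 in 20 sets (15.7 here), and Tbx3 array 2 accounted for 8. In this array Ccl21c (7.32, against 8.21 to 8.67 in the others), Col16a1 (9.69, against 9.99 to 10.14), Id2 (7.70, against 8.06 to 8.25) and Uchl1 (6.08, against 6.41 to 6.57) were lowest, and Tbx5 (9.11, against 8.26 to 8.44) and Ttn (11.66, against 10.92 to 11.14) were highest, all as log2 levels. Its mean over the sarcomere list was 10.45, above the 10.13 to 10.24 of the others, and over the cell cycle inhibitor list 7.07, below 7.15 to 7.19. Other high values were Cntn2 in Control array 5 (7.05, against 5.68 to 6.05), Cacna1h in Control array 4 (7.40, against 4.74 to 5.09) and Kcnj3 in Control array 3 (9.66, against 8.79 to 8.91). The low values elsewhere were Bmp6 in Control array 1 (6.64), Cox8b in Control array 2 (12.35), Id3 in Control array 3 (7.79), Kcnj3 and the sodium channel family mean in Tbx3 array 4 (7.55 and 5.93), Shox2 in Tbx3 array 3 (5.54), and Sln and the thyroid list mean in Tbx3 array 1 (5.68 and 5.15). The interquartile range of Control array 4 in deposited units, 0.65, lay above the 0.54 to 0.58 of the other Control arrays.

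The mouse Tbx3 probe was lower in the Tbx3 arrays, although the transgene is meant to raise Tbx3. Single arrays with the wrong label are argued against, since 0 of the 12 arrays lay nearer the other group in the probes called without that array. On a scale from 0 at the Control mean to 1 at the Tbx3 mean the Control arrays lay between 0.04 and 0.18 and the Tbx3 arrays between 0.69, for array 2, and 1.14. An exchange of all labels would leave these positions as they are, but it would turn the falls of Nppa (-1.35), Gja1 (-0.95) and Gja5 (-1.93), which Tbx3 is known to repress, into rises. Whether either probe reads the transgene stays open, as neither can be placed relative to it and the dimmer probe changed by 0.017 log2. The Tbx3 probes therefore do not show whether the transgene was expressed, and the source of the lower signal was not tested.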

How the results depend on the processing

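Keeping the repeated rows, reading the table in base 2, leaving out Control array 4 and Tbx3 array 6 together and the erythroid covariate were chosen after seeing the data. In the alternatives compared gene by gene, which leave out the repeated rows and the erythroid covariate, no gene called in 1 direction was called in the other, and no called list reversed. The settings over all 12 arrays gave 1462 to 2073 probes past the threshold, with 1592 in the main analysis, except under stricter thresholds. An adjusted p under 0.01 left 896 probes, 304 genes that rose and 303 that fell, and a change of at least 1.5-fold left 565, 205 and 173, in both cases by construction. Reading the table in base 2 with the 1.5-fold limit left 199, 77 and 67, also by construction, keeping the repeated rows gave 1592 probes, and leaving out Control array 4 and Tbx3 array 6 together gave 1373 probes, with 395 of the 524 rises and 408 of the 527 falls kept. As deposited, without quantile normalization, 482 rises and 479 falls were kept. With the mean of all probes of a gene, 361 and 388 were kept. Leaving out each array in turn gave 1187 (without Tbx3 array 1) to 1613 probes (without Tbx3 array 2), 388 to 558 rises, 388 to 526 falls and 12 to 13 lists.

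The shifts of gene lists depended most on the inter-gene correlation. With an estimated correlation 6 lists passed in place of 13. In arbitrary splits of the 12 arrays the preset correlation called up to 14 lists, and an estimated correlation at most 1. A split with 0 probes past the threshold gave 14 lists with the preset correlation and 0 with an estimated one. Calls with the preset correlation alone are therefore weak evidence of a difference between the groups. The rotation test fry gave 10 lists and the erythroid mean as a covariate gave 10 of the 29 other lists. Under that covariate the sarcomere, proliferation and macrophage lists lost their calls, and the epicardial list gained one (adjusted p = 0.0491). For the genes named in the report and from the families and lists of the observations, 2395 of 2516 values under the alternatives kept direction and side of the threshold, 100 lost the call, 4 gained it and 17 without a call changed sign.

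The replicate numbers do not pair the arrays. Deviations of arrays with the same number correlated between -0.07 and 0.09, and 1 of 6 Tbx3 arrays correlated best with the Control array of its own number. With the replicate block 1580 probes, 525 rises, 509 falls and 13 lists were called, and among the genes named Hbb-b2 gained a call (adjusted p = 0.0314) while Lrrn4 and Slc2a1 lost theirs (0.0514 and 0.0573). With odd and even numbers as a block, a guess at the chips, 1546 probes were called, and 0 differed between odd and even in limma (1805 at an unadjusted p under 0.05). Detection p-values were not used, so signal over background is unknown, and dim probes limit what could be detected. The planned floors and offsets were not run, since no value was at or below 0.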

Other observations

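The tests that compare fibroblast, endothelial and matrix genes in this part were chosen after the result was seen. Of 77 mitochondrial ribosomal protein genes 20 fell, 0 rose and 57 did not pass, and adjusted over the family alone 37 fell. Mrps28, Mrpl55 and Mrps6 fell by 0.57 (SE 0.10), 0.52 (SE 0.10) and 0.57 (SE 0.11), with adjusted p of 0.000384, 0.00085 and 0.00108. The family shifted down (median log2 change -0.23, camera adjusted p = 8.69e-20, and adjusted p = 0.045 with an estimated correlation). In the same arrays the fibroblast list was higher (median log2 change 0.31, camera adjusted p = 6.55e-08, and adjusted p = 0.0339 with an estimated correlation), and so was the erythroid list with the preset correlation alone (0.60, camera adjusted p = 0.00283, but adjusted p = 0.258 with an estimated correlation). Of 76 cytosolic ribosomal protein genes 0 passed in limma under either adjustment, and the family did not shift (median log2 change 0.03, camera adjusted p = 0.409). In the proteasome family Psme4, a proteasome activator, fell by 0.39 (adjusted p = 0.0212, up to 0.07 without any of 4 single arrays, Control 2 and 3 and Tbx3 5 and 6), or by 0.24 with the mean of its probes, the only call among 48 genes under either adjustment, and the shift of the family (camera adjusted p = 0.0498) was lost with an estimated correlation (adjusted p = 0.291). Of 39 Hox genes 0 passed under either adjustment, with no shift (camera adjusted p = 0.903).

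Few genes of nerve and glia passed. Of 8 Schwann cell genes Sox10, a neural crest transcription factor, rose by 0.87 (SE 0.11, adjusted p = 4.86e-06) and Pmp22, a myelin protein, by 0.46 (SE 0.10, adjusted p = 0.00638), and 0 fell, with the same counts adjusted over the list alone. The list shifted up with the preset correlation (median log2 change 0.13, or 0.53 under the stricter filter on dim probes, camera adjusted p = 0.0036), which was lost with an estimated correlation (adjusted p = 0.0805). Of 16 genes of cardiac neurons Uchl1 rose by 0.72 (SE 0.11, adjusted p = 4.2e-05), with 2 rises adjusted over the list alone, and the list did not shift (camera adjusted p = 0.299).

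Chance is unlikely to give counts of probes and genes as large as the real ones. A test with 100 splits of the arrays cannot show a share below 1 of 100, and it does not test a batch that follows the groups. Among 100 splits of the 12 arrays into 6 and 6, only the real one, 1 of 100, gave as many probes (1592, highest other 261), as many rises (524) or as many falls (527). The other splits have no direction of their own, so the larger of the rises and falls of each was set against either count, with 119 as the highest. Chance cannot be excluded for the number of lists called with the preset correlation, 13, since 5 of the 100 splits gave as many and the highest other gave 14. With an estimated correlation the real split, with 6 lists, was again the only 1 of 100, with 1 list in the highest other.

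Rises of 24 of 47 matrix and 6 of 16 fibroblast genes came with falls of 11 of 25 genes of working myocardium, 8 of 33 of fatty acid oxidation and 10 of 53 of oxidative phosphorylation, which a change in the cells of the samples could give, although the last 2 lists did not shift with an estimated correlation (adjusted p of 0.0668 and 0.0525). A lower share of muscle cells alone would raise every other cell type alike. But the mean of the fibroblast list rose by 0.474 log2 more than that of the endothelial list. The exact permutation p was 0.00216 over 924 splits, the smallest they can give, in a test chosen after the result was seen. Every Tbx3 array lay above every Control array in this difference. The margin was very small between Tbx3 array 2 (list means 9.146 and 8.606) and Control array 1 (9.141 and 8.602). List means changed by 0.444 for erythroid, 0.280 for Schwann cell, 0.159 for macrophage and 0.142 for adipocyte genes. They changed by 0.070, 0.069 and 0.065 for lymphocyte, neuron and smooth muscle genes, and by -0.092 and -0.088 for endothelial and epicardial genes. The lymphocyte and neuron lists were dim, with Control means of 6.156 and 5.568 against a median of 5.55 over all probes. Little rise could show in them. The fibroblast and endothelial lists, with Control means of 9.066 and 8.660, argue against a lower share of muscle cells as the only change. Such a share together with other changes of cells was not tested. The quantile normalization added here is argued against by a median matrix change of 0.452 in the table as deposited, against 0.429 after it, while the authors' own processing was not tested. The 5 fibroblast markers brightest in Control had a mean change of 0.483, carried by Dpt (0.88) and Lum (0.83), while Col3a1 (0.35), Fbln1 (0.20) and Dcn (0.15) did not pass (adjusted p of 0.134, 0.537 and 0.604) in their brightest probes, although 2 of 5 Dcn probes were called as rises, and the other markers had a mean of 0.335. These 5 markers rose unevenly, so their mean does not decide whether the Tbx3 samples held more fibroblasts. More fibroblasts stays open as a candidate explanation. So does a change of expression within cells that follows from activated Tbx3, which was not tested.

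DNA linked to a transgene or a difference of strain background may place called genes side by side. The test was written before its result was seen. The largest number of called genes among 20 neighbouring measured genes, ordered by the GRCm38.p6 gene table with tandem copies dropped, was 6, and 10000 shuffles of the calls gave a median of 7 and a highest value of 11, so no large block of changed genes was found. Neighbouring pairs that were both called numbered 80, against a median of 66 in the shuffles, a number reached in 0.0395 of them. A short linked segment with few changed genes stays open.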
